A study of Mus musculus with 2 samples.

How the data were processed

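Single-cell RNA sequencing was done on splenic CD8 T cells of 2 C57BL/6 mice, 33 days after infection with LCMV Cl13, a strain of lymphocytic choriomeningitis virus that establishes chronic infection. The cells had been sorted for binding of the GP33 tetramer, a reagent that stains T cells whose receptor recognises the viral peptide GP33. One 5' library (10x Genomics Chromium, 5' v2 chemistry) was made per mouse. The labels define 1 group with 2 replicates and no treatment or control, so every comparison was made between classes of cells within the same mice.

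The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, in whole numbers and without normalization. Other deposited files hold the cell barcodes and the gene identifiers and symbols in matrix order. Per the labels the authors used Cell Ranger and genome build mm10. The matrix header gives software version 3.0.0, and the filter that chose the barcodes is not stated. The matrices list 31053 genes. Of these identifiers, 30934 were found in GENCODE release M21 for build GRCm38, the source of all coordinates given. The authors' own clusters and T cell receptor libraries were not used here.

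Mouse 1 had 2987 barcodes with 10415563 UMIs, and mouse 2 had 2567 barcodes with 7380065 UMIs. Cells were kept with at least 400 detected genes, mitochondrial UMIs under 10% and fewer UMIs than 5 times the library median, which removed 95 and 75 barcodes. Scrublet, as run within scanpy, marked 0 and 5 cells as doublets at its own threshold. By a rule fixed in advance for that outcome, the highest-scoring 0.8% per 1000 cells were removed instead, 67 and 50 cells. This left 2825 and 2442 cells, 5267 in all. The libraries shared 16 barcodes.

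Counts were scaled to 10000 per cell and log-transformed. Clustering used the 2000 most variable genes, 30 principal components, 20 neighbours and Leiden resolution 0.8 with seed 1 and no centring by mouse. The 364 genes of the 14 fixed gene lists, 662 T cell receptor and immunoglobulin segments, Xist and Y-linked genes were left out of the variable genes. A cluster took the name of a cell type when at least 3 of its 10 leading genes were markers of that type, and more than of any other type. Leading genes were detected in at least 10% of the cluster's cells and ranked by fold change with a pseudocount of 0.1 per 10000. Marker sets covered progenitor, naive, effector, terminal, cycling and interferon-responding T cells, and B, plasma, myeloid or dendritic, neutrophil, NK, CD4 T, gamma-delta T, erythroid cells and platelets. The marker sets were fixed before the data were examined, and the rule of 3 among 10 was set after the clusters had first been viewed. Cluster 3 reached the effector name on exactly 3 markers once receptor segments were passed over among leading genes, and an alternative leaves it out.

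For each contrast, UMIs were summed per mouse and class, giving 4 sums. Genes were tested with edgeR's quasi-likelihood F test after TMM scaling and filterByExpr, with mouse as the replicate block, since both classes of a pair come from the same animal. Benjamini-Hochberg adjustment covered the tested genes that were left out of the clustering, with a threshold of 0.05. A contrast has 1 residual degree of freedom, so its spread is borrowed largely across genes. An adjusted p of this test for a gene speaks for these 2 mice and for class borders drawn on the same cells. Levels are TMM-scaled CPM, the UMIs of a gene divided by the sum's total times its TMM factor and put on a common scale, given as mean ± SD over the 2 mice. SE means a standard error worked back from the test, the absolute log2 fold change divided by the square root of its F value. It rests on spread borrowed across genes, so it can be smaller than the spread of a gene between the 2 mice. Positive log2 fold changes mean higher in the class named first.

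The 14 gene lists, also fixed before the data were examined, were inhibitory receptors, cytotoxic and effector molecules, costimulatory receptors, transcription factors, trafficking and adhesion, cytokine receptors, NK receptors, immediate early genes, the BCL-2 family, antigen presentation on MHC class I, glycolysis, nuclear oxidative phosphorylation, cytosolic ribosomal proteins and mitochondrially encoded genes. Each was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, two-sided, adjusted over the 14 lists of a contrast. At the preset correlation camera sets list members against the other genes as if nearly independent, so its p does not measure spread between mice. The estimated correlation rests on 1 residual degree of freedom. With it, camera also missed simulated lists with a true shift (p from 0.0711 to 0.110). Named genes followed a rule fixed in advance. From each list came the 2 members with the smallest adjusted p among those that moved the same way in both mice. Outside the lists came the 5 highest and 5 lowest log2 fold changes among genes left out of the clustering and past the threshold, moving the same way in both mice and reaching 50 CPM in 1 class. Predicted genes and receptor segments were passed over. Reads of near-identical genes, among them the MHC class I, Klra, Trbv13, Bcl2a1 and ribosomal protein families, can be credited to the wrong copy or dropped. Where 2 gene identifiers share a symbol, as for Aldoa, they were kept apart.

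Shares of cells carry exact Clopper-Pearson 95% intervals, except that a count of 0 is given the share that 3 counts would make. Folds against a count of 0 use a floor of 3 counts. Intervals, limits and floors cover counting error only. Cells of 1 clone are not independent, so no test was run across cells. Trbv usage was taken over cells with UMIs of exactly 1 of 35 Trbv segments. Shares of cells with a UMI of S1pr1, Klrk1 or Gzmb were measured after thinning each cell to 1500 UMIs, since depth differs between classes, and cells below that depth were left out.

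Alternatives fixed before the data were examined covered the cell filter and doublets, Leiden resolutions 0.5 and 1.2, 1000 and 3000 variable genes, centring by mouse, 287 cell cycle genes left out of the clustering, count splitting, fixed gates on Tcf7, Cx3cr1, Cd101 and Cxcr6 without Mki67 and Top2a in place of clusters, scaling by DESeq2's size factors, the DESeq2 Wald test, no count filter, no replicate block, all classes in a single fit, and each mouse left out. Chosen after seeing the data were library size scaling, thinning before clustering, leaving out a cell rich in S100a9, leaving cluster 3 out of the effector-like class, and the 3 contrasts described under other observations. The pipeline was tested on simulated data with known changes added to sums of the same sizes. At 4-fold changes, edgeR recovered 96.7%, 95.2%, 96.8%, 57.8% and 89.1% of changed genes in the order of the contrasts reported. At 1.5-fold it recovered 19.0%, 23.1%, 44.6%, 10.9% and 32.3%. Among its calls for effector-like against terminal-like cells, 8.66% were false. DESeq2 recovered 55.0%, 56.5%, 71.4%, 29.7% and 65.6% at 4-fold and made 0 false calls in each contrast. The simulation gave all genes the same spread, made changes alike in both mice and kept the classes fixed. It therefore does not cover spread that differs by gene or class borders drawn on the same cells.

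Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, scipy 1.17.1, numpy 2.4.6, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.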

Results

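Gene expression was measured in single splenic CD8 T cells that bound the GP33 tetramer, taken from 2 mice on day 33 of LCMV Cl13 infection, with 1 library per mouse. Mouse 1 gave 2987 cell barcodes with a median of 2610 UMIs and 1098 genes, and mouse 2 gave 2567 barcodes with a median of 2287 UMIs and 1009 genes. The libraries held 10415563 and 7380065 UMIs. After filtering, 2825 and 2442 cells remained. The summed profiles of the libraries correlated across 10123 genes with Pearson's r = 0.987 and Spearman's rho = 0.987, where genes are not independent replicates.

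The cells formed 12 clusters, most of them T cells in the states known from chronic infection. Cluster 4 was named progenitor-like for Xcl1, Id3, Il7r, Slamf6 and Tcf7, markers of the self-renewing pool of exhausted T cells. Clusters 1 and 3 were named effector-like, cluster 1 for S1pr5, Klre1, Zeb2, Gzma and Klrg1 and cluster 3 for Lgals3, Vim and Itgax. Cluster 5 was named terminal-like for Cd7, Cd160, Rgs1 and Abi3. The other T cell clusters were interferon-like (cluster 7), cycling-like (clusters 8 to 10) and naive-like (cluster 6, with Dapl1, Igfbp4 and Ccr7 among its leading markers). Cluster 2, led by Nccrp1, Ier3, Ctla2a and Cxcr3, did not earn a name. Small clusters of myeloid or dendritic cells (34 and 11 cells in mouse 1 and mouse 2) and B cells (21 and 11 cells) were left out of the T cell comparisons.

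Effector-like cells were the most frequent class in both mice, at 55.2% of cells in mouse 1 (95% interval 53.3 to 57.0) and 45.8% in mouse 2 (43.8 to 47.8), or 50.5% ± 6.60 (SD, n = 2). Progenitor-like cells made up 9.45% (8.40 to 10.6) and 15.5% (14.1 to 17.0), and terminal-like cells 5.73% (4.91 to 6.66) and 12.4% (11.1 to 13.8). The means were 12.5% ± 4.29 for progenitor-like and 9.07% ± 4.72 for terminal-like cells. Cycling-like cells averaged 5.43% ± 1.19, naive-like cells 4.19% ± 0.216, interferon-like cells 2.73% ± 1.196 and the unnamed cluster 2 14.2% ± 0.493. Myeloid or dendritic cells averaged 0.827% ± 0.533 and B cells 0.597% ± 0.207. The intervals of the mice did not overlap for effector-, progenitor-, terminal- and interferon-like cells (3.58% and 1.88% for the last) or for myeloid or dendritic cells, so these shares differed between animals by more than counting error. The mean effector-like share ranged between settings from 22.6% with fixed gates to 63.2% with 3000 variable genes. The effector gate asked for a Cx3cr1 UMI in each cell, so its share also follows how often that gene is detected.

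**Figure D1:**
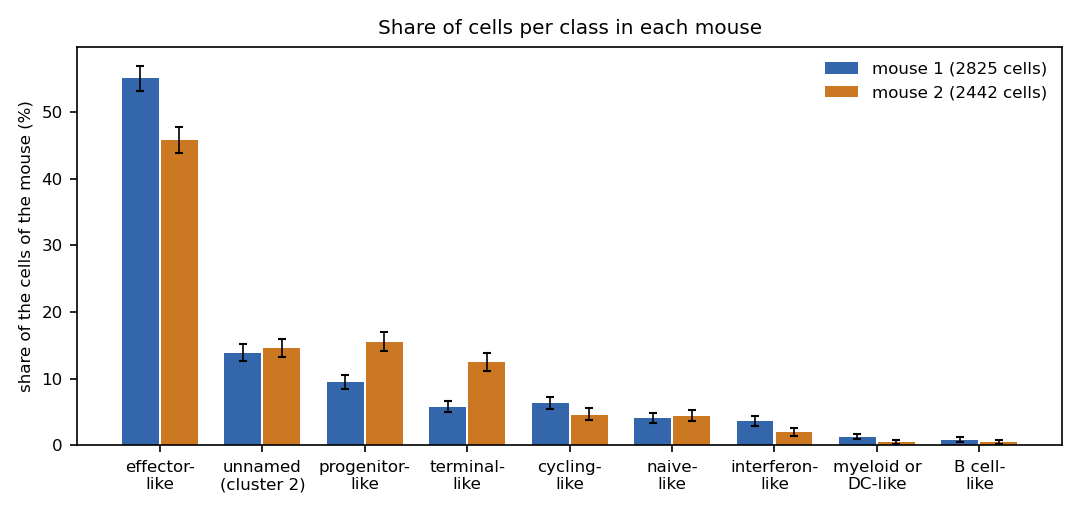
Share of each mouse's cells in each class, in percent, for mouse 1 (blue) and mouse 2 (orange); bars start at 0 and error bars are exact 95% intervals for counting error. Effector-like cells are the tallest pair at 55.2% and 45.8%, and terminal-like cells stand at 5.73% and 12.4%.

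Progenitor-like and terminal-like cells were named by markers of the self-renewing and the most differentiated exhausted cells of chronic infection. Neither self-renewal nor an order of differentiation was measured here. Terminal-like cells carried more inhibitory receptor and cytotoxic transcripts, and progenitor-like cells carried more ribosomal protein transcripts and more S1pr1 and Bcl2. Gzmb, encoding the cytotoxic protease granzyme B, stood at 51.5 ± 29.4 CPM in progenitor-like and 490 ± 77.5 in terminal-like cells (SD, n = 2; log2 fold change -3.30, SE 0.163, adjusted p = 2.61e-15). S1pr1, the receptor that guides lymphocytes out of lymphoid tissue, stood at 99.5 ± 30.5 against 8.85 ± 0.875 (log2 fold change 3.57, SE 0.312, adjusted p = 4.97e-10). Of 5704 genes, 639 passed the threshold of edgeR's quasi-likelihood test, 389 higher and 250 lower in progenitor-like cells, and 638 of the 639 moved the same way in both mice. Genes on which the mice agree pass this test more readily. Such counts of shared direction, here and in the later comparisons, are thus no separate evidence of replication.

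Inhibitory receptors were lower in progenitor-like cells for 6 of 8 members, with 0 higher and 2 not past the threshold. Lag3 stood at 80.8 ± 27.4 against 253 ± 53.6 CPM and Pdcd1, which encodes PD-1, at 59.5 ± 8.76 against 190 ± 18.8 (log2 fold changes -1.67 and -1.68). The same 6 of 8 were lower when adjusted over the list alone, and camera called the list lower (adjusted p = 3.16e-07; adjusted p = 0.398 with an estimated correlation). Of 16 cytotoxic and effector molecules, 13 were lower, 1 was higher and 2 did not pass, with the same counts when adjusted over the list alone. Besides Gzmb, the chemokine gene Ccl5 fell by 1.36 on the log2 scale. Camera called this list lower too (adjusted p = 1.99e-55; adjusted p = 0.378 with an estimated correlation). Antigen presentation on MHC class I was lower for 8 of 12 members, 0 higher and 4 not passed (9 lower when adjusted over the list alone). Tap2, a subunit of the peptide transporter, had a log2 fold change of -0.76 and Psmb8, an immunoproteasome subunit, of -0.41 (camera adjusted p = 1.85e-05; adjusted p = 0.425 with an estimated correlation). Of 21 transcription factors, 9 were lower, 3 higher and 9 not passed (11 lower and 5 higher when adjusted over the list alone). Id2, a regulator of effector differentiation, stood at 378 ± 6.37 against 941 ± 52.2 CPM, while Zbtb32 stood at 53.6 ± 2.95 against 12.1 ± 0.361 (camera adjusted p = 0.0193; adjusted p = 0.494 with an estimated correlation).

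Cytosolic ribosomal proteins were higher in progenitor-like cells for 77 of 82 members, 0 lower and 5 not passed, and again 77 when adjusted over the list alone. Rps20 and Rps19 had log2 fold changes of 1.22 and 1.15 (camera adjusted p = 2.53e-285; adjusted p = 0.378 with an estimated correlation). Mitochondrially encoded genes were higher for 12 of 13 members, 0 lower and 1 not passed (13 higher when adjusted over the list alone), led by mt-Co3 and mt-Co1 at 0.75 and 0.52 (camera adjusted p = 8.38e-13; adjusted p = 0.378 with an estimated correlation). The median mitochondrial share of UMIs was 0.889% and 1.08% in progenitor-like and 0.628% and 0.848% in terminal-like cells of mouse 1 and mouse 2. Among NK receptors 2 of 3 were higher, 0 lower and 1 not passed (2 higher when adjusted over the list alone): Klrk1, encoding the activating receptor NKG2D, at 107 ± 20.01 against 16.3 ± 3.69 CPM, and Klrd1 with a log2 fold change of 0.84 (camera adjusted p = 0.0307; adjusted p = 0.503 with an estimated correlation). The terminal-like Klrk1 signal rests on few cells and could not be told apart from background, as shown further on. With fixed gates in place of clusters, Klrk1, Klrd1 and the cytokine receptor Il18r1 reversed to -0.75, -0.11 and -0.32. The gates go by UMIs of single genes and set no naive-like cells apart, so they do not hold the same cells as the clusters.

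The remaining lists moved in part or both ways and were not called. Trafficking and adhesion genes were higher for 9 of 18 and lower for 5 with 4 not passed (10 and 6 when adjusted over the list alone, 7 and 7 with library size scaling), with the integrin gene Itgb1 at 752 ± 45.9 against 173 ± 6.23 CPM. Immediate early genes were higher for 6 and lower for 3 of 15, with 6 not passed (7 and 3 over the list alone), Fosb rising by 2.47 and Dusp2 falling by 1.16 on the log2 scale. In the BCL-2 family 2 members were higher, 3 lower and 5 not passed of 10 (2 and 3 over the list alone). Survival gene Bcl2 stood at 342 ± 11.6 against 168 ± 20.2 CPM and Bcl2a1b had a log2 fold change of -1.14. Glycolysis genes were higher for 4, lower for 0 and not passed for 10 of 14 (6 higher and 1 lower over the list alone), with Eno1 at 0.68 and Tpi1 at 0.97, and the list's median turned negative with library size scaling. Costimulatory receptors (2 higher, 3 lower, 7 not passed of 12), cytokine receptors (2, 3 and 10 of 15) and nuclear oxidative phosphorylation (3, 2 and 69 of 74) had small counts, and the medians of the latter pair also turned negative with library size scaling. For nuclear oxidative phosphorylation the test pointed down and the median up, and 0 were higher and 16 lower with library size scaling. Adjusted over the list alone these counts were 2 higher and 5 lower, 3 and 4, and 2 and 2. Their named members were Slamf7 and Tnfrsf1b (-1.02 and -1.06), Il18r1 and Il21r (1.41 and -1.21), and Atp5g2 and Ndufb8 (0.34 and -0.53). Outside the lists and the clustering genes, Nsg2, Cd9, Satb1, Pdlim1 and Bmyc were highest in progenitor-like cells (log2 fold changes 4.65, 4.59, 3.30, 3.28 and 2.87). Nsg2 and Cd9 are among the markers that named the class, and Satb1 is among the naive markers. Plekhf1, Glrx, Slc16a6, Hip1 and Pelo were lowest (-3.01, -2.49, -1.89, -1.82 and -1.80). DESeq2's Wald test called 170 genes, all shared with edgeR and in the same direction. With library size scaling in place of TMM, 268 of 790 called genes were higher in progenitor-like cells (33.9%, against 60.9%).

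**Figure D2:**
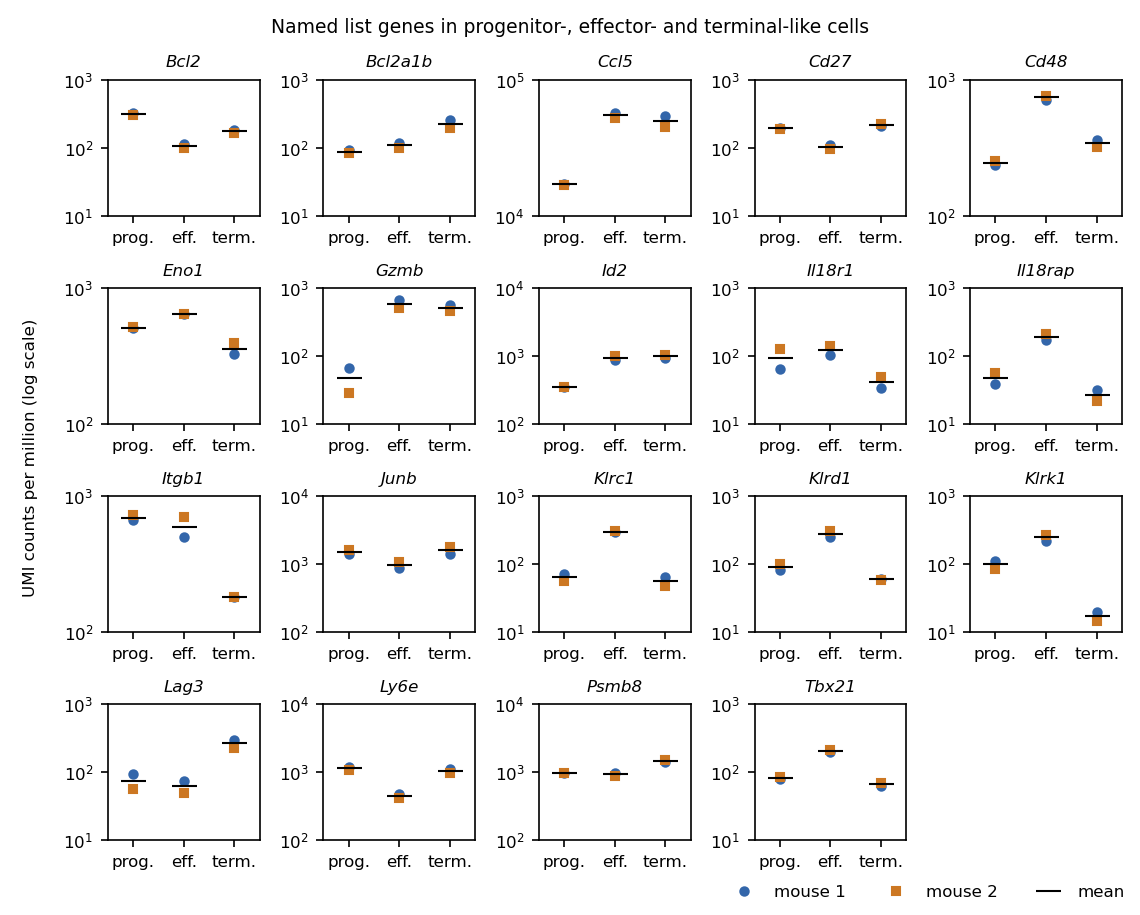
CPM without TMM scaling (log axis) of 19 genes of the fixed lists in progenitor-, effector- and terminal-like cells; each point is 1 mouse and the black line is the mean of both. Lag3 is highest in terminal-like cells, Klrk1, Il18rap and Tbx21 in effector-like cells and Bcl2 in progenitor-like cells, in both mice.

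Effector-like cells carried more NK receptor and interleukin 18 receptor transcripts and fewer inhibitory receptor transcripts than terminal-like cells. Klrk1 stood at 245 ± 31.3 CPM in effector-like and 17.3 ± 3.82 in terminal-like cells (log2 fold change 3.91, SE 0.214, adjusted p = 1.52e-28). The terminal-like Klrk1 signal could not be told apart from background, as shown further on, so this fold may be a lower limit. Lag3 stood at 62.0 ± 18.3 against 268 ± 55.4 (log2 fold change -2.12, SE 0.130, adjusted p = 2.27e-25). Of 6984 genes, 970 passed, 492 higher and 478 lower in effector-like cells, and 964 of the 970 moved the same way in both mice.

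All 6 NK receptors were higher, over all genes and adjusted over the list alone, with Klrc1 at 299 ± 2.84 against 57.7 ± 13.7 CPM (camera adjusted p = 2.10e-14; adjusted p = 0.526 with an estimated correlation). Inhibitory receptors were lower for 6 of 11 members, with 0 higher and 5 not passed, and for 6 when adjusted over the list alone. Tigit stood at 99.9 ± 22.6 against 303 ± 37.3 CPM (camera adjusted p = 5.37e-12; adjusted p = 0.526 with an estimated correlation). Antigen presentation on MHC class I was lower for 9 of 12 members, higher for 2 and not passed for 1 (10 lower and 2 higher when adjusted over the list alone), with Psmb10 at -0.72 and Psmb8 at -0.69 (camera adjusted p = 1.54e-06; adjusted p = 0.526 with an estimated correlation). Cytosolic ribosomal proteins were lower for 53 of 82, higher for 6 and not passed for 23 (58 and 7 when adjusted over the list alone), with Rpl12 at -0.80 and Rps15a at -0.77 (camera adjusted p = 2.16e-67; adjusted p = 0.526 with an estimated correlation). Immediate early genes were lower for 7, higher for 6 and not passed for 4 of 17 (8 and 6 when adjusted over the list alone). Ier3 had a log2 fold change of -2.15 and Junb of -0.73 (camera adjusted p = 0.0144; adjusted p = 0.571 with an estimated correlation).

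Lists that camera did not call still held large single changes. Tbx21, which encodes the transcription factor T-bet, stood at 202 ± 4.70 against 66.6 ± 2.52 CPM, and Tox, a regulator of exhaustion, at 115 ± 9.99 against 199 ± 18.2. Their list had 3 higher, 8 lower and 13 not passed of 24 (4 and 9 adjusted over the list alone). Of 15 cytokine receptors, 4 were higher, 4 lower and 7 not passed, with the same split over the list alone. The interleukin 18 receptor genes Il18rap and Il18r1 had log2 fold changes of 2.92 and 1.505. Trafficking and adhesion genes were higher for 9, lower for 7 and not passed for 2 of 18, and the same over the list alone, with Itgb1 at 1.75 and Ly6e at -1.25. Cytotoxic molecules were lower for 7, higher for 2 and not passed for 7 of 16 (7 and 3 over the list alone). Tnf stood at 57.0 ± 15.2 against 148 ± 8.57 CPM, and Gzmk had a log2 fold change of -0.63. Costimulatory receptors were lower for 6, higher for 1 and not passed for 5 of 12 (6 and 2 over the list alone), Cd27 at -1.11 and Cd48 at 1.13. In the BCL-2 family 4 were lower, 2 higher and 6 not passed of 12 (5 and 4 over the list alone), with Bcl2a1b at -1.05 and Bcl2 at -0.75, and the mean of this list was above 0 while its median and test pointed down. Glycolysis genes were higher for 5, lower for 4 and not passed for 5 of 14 (6 and 4 over the list alone), Slc2a1 at 1.44 and Eno1 at 0.79. Mitochondrially encoded genes were higher for 2 and not passed for 11 of 13 (2 over the list alone), mt-Co2 at 0.19 and mt-Co3 at 0.18, calls that were lost in 7 and 11 of 18 other settings. Nuclear oxidative phosphorylation was higher for 2, lower for 7 and not passed for 66 of 75, and the same over the list alone, Atp5h at 0.55 and Cox8a at -0.23, with a mean just below 0 and a median above it.

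Outside the lists and the clustering genes, Rap1gap2, Lgals1, Rara, Txndc5 and Stard10 were highest in effector-like cells (log2 fold changes 4.94, 2.99, 2.95, 2.85 and 2.64), where Lgals1 is an effector marker used for naming. Pacsin1, Spint2, Apol7e, Aim2 and Pgs1 were lowest (-3.02, -2.21, -1.99, -1.82 and -1.73). Fewer genes passed with DESeq2's Wald test (221), without the replicate block (552), with count splitting (473) and with fixed gates (210).

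Against effector-like cells, the most frequent class, progenitor-like cells carried more Bcl2 and ribosomal protein transcripts and fewer cytotoxic and NK receptor transcripts. Bcl2 stood at 341 ± 14.5 CPM in progenitor-like and 99.1 ± 11.4 in effector-like cells (log2 fold change 1.78, SE 0.0951, adjusted p = 6.29e-22). Gzmb stood at 51.4 ± 29.8 against 552 ± 123 (log2 fold change -3.46, SE 0.121, adjusted p = 3.03e-29). Of 7131 genes, 1367 passed, 731 higher and 636 lower in progenitor-like cells, and 1362 of the 1367 moved the same way in both mice.

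Cytosolic ribosomal proteins were higher for 79 of 82 members, 0 lower and 3 not passed, and 79 when adjusted over the list alone. Rpl12 and Rps20 had log2 fold changes of 1.48 and 1.45 (camera adjusted p = 3.03e-207; adjusted p = 0.341 with an estimated correlation). All 13 mitochondrially encoded genes were higher, over all genes and adjusted over the list alone, with mt-Nd4l at 0.83 and mt-Co3 at 0.58 (camera adjusted p = 1.78e-17; adjusted p = 0.341 with an estimated correlation). The median mitochondrial share of UMIs in effector-like cells was 0.695% and 0.884%, below the shares given for progenitor-like cells. Cytotoxic molecules were lower for 10 of 16, higher for 1 and not passed for 5 (12 and 2 when adjusted over the list alone), Ccl5 at -1.48 (camera adjusted p = 1.58e-13; adjusted p = 0.341 with an estimated correlation). All 6 NK receptors were lower, over all genes and adjusted over the list alone, Klrc1 at -2.03 and Klrd1 at -1.39 (camera adjusted p = 2.66e-10; adjusted p = 0.341 with an estimated correlation). Immediate early genes were higher for 9, lower for 3 and not passed for 4 of 16 (10 and 4 when adjusted over the list alone). Jun and Junb, subunits of the AP-1 factor, had log2 fold changes of 1.46 and 0.83 (camera adjusted p = 0.000293; adjusted p = 0.420 with an estimated correlation).

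Inhibitory receptors split in this comparison, with 4 higher, 4 lower and 2 not passed of 10, the same over the list alone (2 higher and 5 lower with library size scaling), and a test that pointed up against a median below 0. Ctla4 stood at 39.96 ± 2.90 against 8.92 ± 2.45 CPM, and Havcr2, which encodes TIM-3, had a log2 fold change of -2.85. Costimulatory receptors split too, with 6 higher, 6 lower and 1 not passed of 13 (6 and 7 over the list alone), Cd27 at 1.10 and Cd48 at -1.40, with a mean above 0 and a median below it. Transcription factors were higher for 7, lower for 6 and not passed for 11 of 24 (7 and 8 over the list alone, 5 and 12 with library size scaling), Tbx21 at -1.11 and Id2 at -1.21. Trafficking and adhesion genes were lower for 9, higher for 6 and not passed for 3 of 18, the same over the list alone, Ly6e at 1.56 and Ly6a at 0.89. Cytokine receptors were lower for 5, higher for 3 and not passed for 9 of 17 (5 and 6 over the list alone), Il18rap at -1.79 and Ifngr1 at -0.63, and the test pointed down with a median above 0. The BCL-2 family had 1 higher, Bcl2, with 2 lower and 9 not passed of 12, the same over the list alone, Pmaip1 at -1.54. MHC class I genes had 2 higher, 2 lower and 8 not passed of 12 (3 and 2 over the list alone), H2-Q7 at -0.37 and H2-D1 at -0.33, but 0 higher and 8 lower with library size scaling. Glycolysis had 4 higher, 1 lower and 9 not passed of 14, the same over the list alone, Gpi1 at 0.45 and Gapdh at 0.30, and 2 higher and 5 lower with library size scaling. Nuclear oxidative phosphorylation had 8 higher, 3 lower and 64 not passed of 75 (8 and 2 over the list alone), Atp5g2 at 0.45 and Cox7a2l at 0.41, and 3 higher and 32 lower with library size scaling.

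Outside the lists and the clustering genes, Nsg2, Rgs10, Bmyc, Cd9 and the growth regulator Myc were highest in progenitor-like cells (log2 fold changes 6.00, 3.70, 2.88, 2.79 and 2.68). D1Ertd622e, Tmem163, Wdr95, Rap1gap2 and Lgals1 were lowest (-2.25, -2.24, -2.10, -1.91 and -1.75). Nsg2, Cd9 and Lgals1 are markers used for naming. Fewer genes passed with DESeq2's Wald test (316), without the replicate block (853) and with count splitting (732). With library size scaling, 453 of 1923 called genes were higher in progenitor-like cells (23.6%, against 53.5%).

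**Figure D3:**
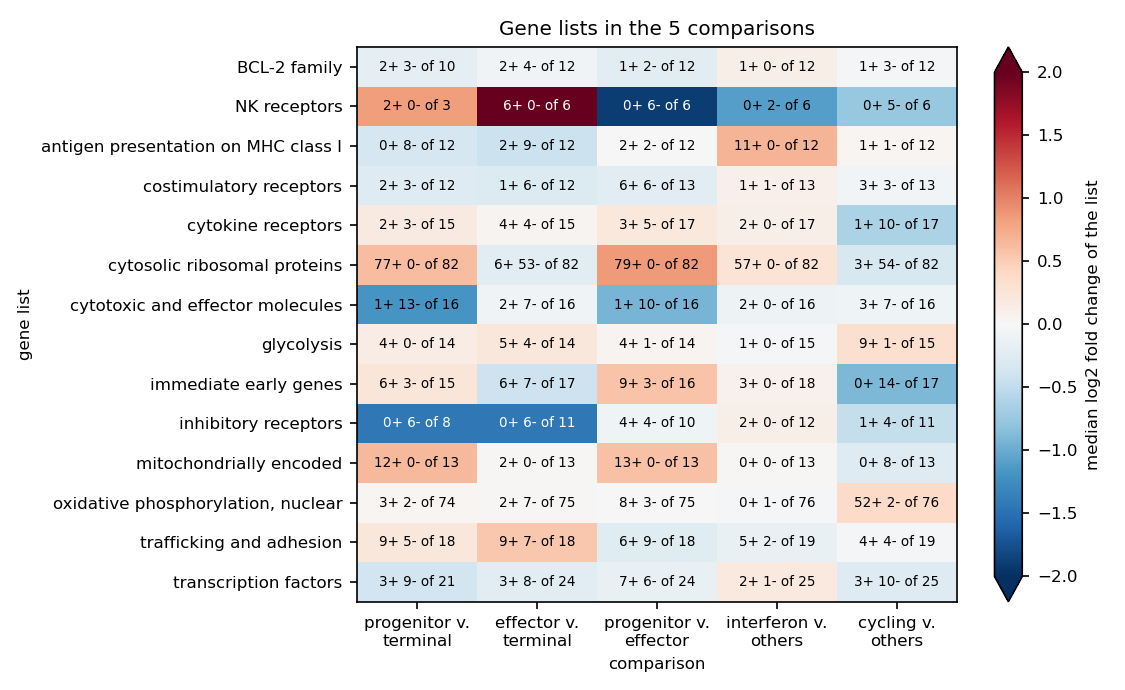
The 14 gene lists in the 5 comparisons; colour is the median log2 fold change of a list's members (first class over the other, saturating at 2 in either direction) and text gives the members past the threshold, higher (+) and lower (-), of those tested. NK receptors are darkest, 6 of 6 higher in effector-like against terminal-like cells; with library size scaling the medians of glycolysis and oxidative phosphorylation turn negative in both progenitor-like columns, as do cytokine receptors in the first column, MHC class I genes in cycling-like cells and the faint positive medians of the interferon-like column other than transcription factors and ribosomal proteins.

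Interferon-like cells, named by their interferon-induced genes, were compared with the other named T cell classes together. They carried more Ly6a, Ly6e and MHC class I antigen presentation transcripts. Ly6a stood at 2354 ± 164 CPM in interferon-like cells and 642 ± 140 in the others (log2 fold change 1.87, SE 0.0784, adjusted p = 2.58e-118). Tapbp, the bridge between the peptide transporter and MHC class I, stood at 580 ± 50.6 against 213 ± 14.7 (log2 fold change 1.44, SE 0.120, adjusted p = 2.99e-30). Of 7718 genes, 320 passed, 253 higher and 67 lower, and 316 of the 320 moved the same way in both mice. The class held 101 and 46 cells. Of the UMIs of the pool, effector-like cells gave 4556810 of 7839290 in mouse 1 and 2695510 of 5722000 in mouse 2. Effector-like cells were low in Ly6e, at 444 CPM without TMM scaling against 1133 in progenitor-like and 1039 in terminal-like cells. They were also low in Lag3 and ribosomal protein transcripts and high in NK receptors. Differences in these genes can thus partly reflect the make-up of the pool.

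Antigen presentation on MHC class I was higher for 11 of 12 members, 0 lower and 1 not passed, and 11 when adjusted over the list alone, with H2-T23 at a log2 fold change of 0.94 (camera adjusted p = 4.78e-19; adjusted p = 0.590 with an estimated correlation). Cytosolic ribosomal proteins were higher for 57 of 82, 0 lower and 25 not passed (72 when adjusted over the list alone), with Rps27 at 0.42 and Rplp1 at 0.40 (camera adjusted p = 1.42e-55; adjusted p = 0.590 with an estimated correlation), and 18 were higher with library size scaling. NK receptors were lower for 2 of 6, 0 higher and 4 not passed (5 lower when adjusted over the list alone), Klrc1 at -0.86 (camera adjusted p = 0.000128; adjusted p = 0.679 with an estimated correlation). Klra3 had 0 UMIs in interferon-like cells of both mice and 187 in the others, at least 2.31-fold lower by a floor of 3 counts over both mice, a call lost in 8 of 16 other settings. Inhibitory receptors were higher for 2 of 12, 0 lower and 10 not passed (3 over the list alone), Lag3 at 1.26 and Pdcd1 at 0.67, the latter call lost in 12 of 17 other settings. Trafficking and adhesion genes were higher for 5, lower for 2 and not passed for 12 of 19 (5 and 5 over the list alone, 3 and 5 with library size scaling), Ly6e at 1.21, and the median lay below 0 while the mean and test pointed up. Immediate early genes were higher for 3, with 0 lower and 15 not passed of 18 (3 over the list alone), Jun at 0.80 and Junb at 0.57.

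Cytokine receptors were higher for 2, 0 lower and 15 not passed of 17 (2 higher and 2 lower over the list alone): Il12rb1 at 1.71 and Il10ra, the interleukin 10 receptor, at 1.03. Cytotoxic molecules were higher for 2, 0 lower and 14 not passed of 16 (2 and 1 over the list alone), Tnfsf10, which encodes the death ligand TRAIL, at 1.29 and Cst7 at 0.44, with a median below 0 against a mean above it, and 0 higher and 3 lower with library size scaling. Transcription factors were higher for 2, lower for 1 and not passed for 22 of 25, the same over the list alone, Hif1a at 0.77 and Bhlhe40 at -0.88. Costimulatory receptors had 1 higher, 1 lower and 11 not passed of 13 (3 and 1 over the list alone), Cd27 at 0.75 and Cd48 at -0.43. The BCL-2 family had 1 higher, 0 lower and 11 not passed of 12, the same over the list alone, with Bcl2a1b at 0.69 and Bcl2 not past the threshold at 0.44 (adjusted p = 0.179), and the mean lay below 0 while the median and test pointed up. Glycolysis had 1 higher, 0 lower and 14 not passed of 15, the same over the list alone, with Aldoa at 0.55 and Slc2a1 not past the threshold at -1.65 (adjusted p = 0.186). Nuclear oxidative phosphorylation had 0 higher, 1 lower and 75 not passed of 76 (0 and 0 over the list alone), Atp5h at -0.31 and Ndufa3 not past the threshold at 0.31 (adjusted p = 0.0955). None of the 13 mitochondrially encoded genes passed edgeR's test, over all genes or over the list alone, with mt-Nd2 at 0.34 and mt-Atp6 at 0.24 (adjusted p = 0.252 and 0.148). Several calls of this paragraph were lost in many of 17 other settings, Cst7 in 14, Hif1a in 13, Tnfsf10 in 12, Cd48 in 9, Bcl2a1b in 8 and Atp5h in 7. With library size scaling, the medians of inhibitory receptors, immediate early genes, cytokine receptors, costimulatory receptors, the BCL-2 family and mitochondrially encoded genes turned from just above 0 to below it.

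Outside the lists and the clustering genes, the interferon-induced genes Iigp1, Cmpk2, Tgtp1 and Oas3 were highest (log2 fold changes 4.26, 3.63, 3.31 and 3.05), Oas3 being a marker used for naming. S100a9 also ranked among the highest, with 152 UMIs against 0, at least 1366-fold by the floor, but 151 of the 152 UMIs (99.3%) lay in 1 cell of mouse 1 that held all 135 UMIs of S100a8, and without that cell 328 genes passed, 256 higher and 72 lower. The cell cycle genes Cenpw, Cdc25b and Racgap1 were among the lowest, with Lgals1 and Fkbp2 (-1.69, -1.66, -1.34, -1.07 and -1.05), the call on Fkbp2 lost in 10 of 17 other settings. The pool they were compared with included the cycling-like cells, so low cell cycle genes here say nothing particular about interferon-like cells. Fewer genes passed with DESeq2's Wald test (76), without the replicate block (169) and with count splitting (128). With library size scaling, 170 of 312 called genes were higher (54.5%, against 79.1%).

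Cycling-like cells were likewise compared with the other named T cell classes together. They carried more transcripts for nuclear oxidative phosphorylation and glycolysis, and fewer for immediate early genes, cytokine receptors and Bcl2. The mitotic gene Hmmr, among the leading genes of cluster 9, had 233 UMIs in cycling-like cells and 0 in the others, at least 439-fold higher by a floor of 3 counts over both mice. The clusters were drawn on cell cycle genes of the same cells, so this fold follows in part from the grouping. The others leave out the unnamed cluster 2. Bcl2 stood at 41.9 ± 11.1 against 163 ± 7.02 CPM (log2 fold change -1.89, SE 0.152, adjusted p = 3.70e-33). Of 7863 genes, 2455 passed, 1591 higher and 864 lower, and 2449 of the 2455 moved the same way in both mice. Cycling-like cells were deeper, with a median of 7907 and 6497.5 UMIs against 2384 and 2063 in effector-like cells. Effector-like cells gave 4556810 of the 6812450 UMIs of this pool in mouse 1 and 2695510 of 5136650 in mouse 2. Lower NK receptors in cycling-like cells can thus partly reflect the make-up of the pool.

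Nuclear oxidative phosphorylation was higher for 52 of 76 members, lower for 2 and not passed for 22 (58 and 2 when adjusted over the list alone), Cox5b at 0.90 and Cox5a at 0.85 (camera adjusted p = 6.33e-09; adjusted p = 0.487 with an estimated correlation). Glycolysis was higher for 9 of 15, lower for 1 and not passed for 5, the same when adjusted over the list alone, with Tpi1 at 1.17 and Gapdh at 1.04 (camera adjusted p = 0.00324; adjusted p = 0.487 with an estimated correlation). Immediate early genes were lower for 14 of 17, 0 higher and 3 not passed (16 when adjusted over the list alone). Junb stood at 465 ± 13.7 against 1144 ± 189 CPM and Btg2, which restrains proliferation, at 153 ± 46.4 against 331 ± 66.0 (camera adjusted p = 5.63e-12; adjusted p = 0.487 with an estimated correlation). Cytokine receptors were lower for 10 of 17, higher for 1 and not passed for 6, the same when adjusted over the list alone, Il18rap at -1.003 and Il18r1 at -0.92 (camera adjusted p = 0.00107; adjusted p = 0.487 with an estimated correlation). NK receptors were lower for 5 of 6, 0 higher and 1 not passed, the same when adjusted over the list alone, Klra9 at -3.34 and Klrd1 at -0.76 (camera adjusted p = 0.000504; adjusted p = 0.487 with an estimated correlation). Cytotoxic molecules were lower for 7, higher for 3 and not passed for 6 of 16, the same when adjusted over the list alone. Ifng, encoding interferon gamma, stood at 180 ± 26.7 against 420 ± 55.1 CPM, and Gzmk at 842 ± 87.0 against 453 ± 54.7 (camera adjusted p = 0.00972; adjusted p = 0.487 with an estimated correlation).

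Cytosolic ribosomal proteins were lower for 54 of 82, higher for 3 and not passed for 25 (56 and 5 when adjusted over the list alone), with Rps27 at -1.06 and Rps27l at 1.07 (camera adjusted p = 4.05e-29; adjusted p = 0.487 with an estimated correlation). Mitochondrially encoded genes were lower for 8 of 13, 0 higher and 5 not passed, the same when adjusted over the list alone, mt-Nd2 at -0.51 and mt-Nd4l at -0.43 (camera adjusted p = 0.00147; adjusted p = 0.487 with an estimated correlation). Median mitochondrial shares of UMIs in cycling-like cells were 0.626% and 0.798%. Transcription factors were lower for 10 of 25, higher for 3 and not passed for 12 (11 and 3 when adjusted over the list alone), Klf6 at -1.06 and Bcl11b at -0.82 (camera adjusted p = 0.00617; adjusted p = 0.530 with an estimated correlation). Inhibitory receptors were not called by camera (adjusted p = 0.0566), with 4 lower, 1 higher and 6 not passed of 11, the same over the list alone, Lag3 at -0.82 and Vsir at -0.69. The BCL-2 family had 3 lower, 1 higher and 8 not passed of 12, the same over the list alone, Bcl2l11, which encodes the death inducer BIM, at -2.52. Costimulatory receptors had 3 higher, 3 lower and 7 not passed of 13 (4 and 3 over the list alone), Tnfrsf9 at 1.05 and Cd48 at 0.65, with a mean above 0 against a median and test pointing down. Trafficking and adhesion had 4 higher, 4 lower and 11 not passed of 19, the same over the list alone, Itgb7 at 0.79 and Ly6e at 0.75. MHC class I genes had 1 higher, 1 lower and 10 not passed of 12, the same over the list alone, Psmb9 at 0.61 and H2-T23 at -0.42, with a test pointing down against a median above 0 that turned negative with library size scaling.

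Outside the lists and the clustering genes, Mxd3 (253 UMIs against 4) and Ska1 had log2 fold changes of 8.40 and 7.62, and Pimreg and Cdca5 had 147 and 133 UMIs against 2 each. As for Hmmr, such folds can follow in part from the grouping. Phf1, Akap8l, Pink1, Rnf167 and Ypel3 were lowest (-1.74, -1.34, -1.27, -1.26 and -1.24). Fewer genes passed with DESeq2's Wald test (808) and with count splitting (1516). None of the list calls in the 5 comparisons held with an estimated correlation, where 0 lists had an unadjusted p under 0.05, while fry called 0, 1, 1, 2 and 0 lists in the order of the comparisons. Simulated lists with a true shift were missed with an estimated correlation too, so that test could not decide. The list p values at the preset correlation do not measure spread between mice.

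Shares of cells with a UMI were compared at equal depth. After thinning to 1500 UMIs, Gzmb was seen in 3.94% ± 1.03 of progenitor-like, 49.2% ± 6.70 of effector-like and 38.3% ± 7.40 of terminal-like cells (SD, n = 2). Klrk1 was seen in 11.4% ± 2.07, 29.3% ± 4.05 and 1.80% ± 0.343, and S1pr1 in 12.2% ± 3.55, 15.9% ± 4.04 and 1.07% ± 0.412. The S1pr1 intervals of progenitor- and effector-like cells overlapped in both mice, as did the Gzmb intervals of effector- and terminal-like cells in mouse 1. Without thinning the Gzmb shares were 7.90%, 63.0% and 48.5%. In B cells, which should lack Gzmb and Klrk1, thinned Gzmb was seen in 0 of 21 and 1 of 11 cells and Klrk1 in 1 of 21 and 0 of 11, too few to bound the background tightly. Naive-like cells, which should lack granzyme B, had a Gzmb UMI in 0 of 112 and 0 of 103 thinned cells (which allows shares of up to 2.68% and 2.91%). S1pr1 was seen in 1 of 21 and 3 of 11 B cells and in 14.3% and 20.4% of naive-like cells, types that express it, so no class that should lack S1pr1 was at hand to give its background. Naive-like cells, a type that in mice does not express NKG2D, had a Klrk1 UMI in 1 of 112 and 1 of 103 thinned cells, or 0.893% and 0.971%. The terminal-like Klrk1 share, 2.04% (0.423 to 5.85) and 1.56% (0.426 to 3.94), lay within counting error of these. Resting on 3 of 147 and 4 of 257 cells, it could not be told apart from background, nor shown to be background. Without thinning, Klrk1 was seen in 4.94% and 1.65% of terminal-like cells. The shares of the deeper naive-like cells were then 2.63% and 0.943%. Median depths before thinning were 2953 and 3001 UMIs in B cells, 4299.5 and 3920 in naive-like, 3327 and 2973 in progenitor-like, and 2378 and 2078 in terminal-like cells.

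Usage of T cell receptor beta V segments, which each T cell chooses once, differed between classes and mice. Among 1769 of 2770 T cells of mouse 1 and 1651 of 2420 of mouse 2 with exactly 1 Trbv segment, Trbv13-1 averaged 19.8% ± 4.27, Trbv29 18.5% ± 6.71, Trbv19 13.4% ± 2.31, Trbv5 8.15% ± 1.42 and Trbv13-3 7.90% ± 4.66. UMIs of several segments were found in 833 and 539 further cells. Trbv19 was used by 19.8% (13.0 to 28.3) and 28.6% (22.6 to 35.2) of terminal-like cells against 7.18% (5.67 to 8.94) and 11.7% (9.49 to 14.2) of effector-like cells, with intervals apart in both mice. High Trbv19 usage was not particular to terminal-like cells. It was 18.6% (12.6 to 25.9) and 16.7% (12.3 to 22.0) in progenitor-like, 26.5% and 21.2% in interferon-like and 19.8% and 8.45% in cycling-like cells. Naive-like cells used it at 6.58% and 6.76%. Trbv13-3 was used by 13.5% (11.4 to 15.7) of effector-like against 2.76% (0.757 to 6.91) of progenitor-like cells in mouse 1, where the intervals were apart. In mouse 2 the shares were 6.43% (4.79 to 8.41) and 2.45% (0.904 to 5.25), whose intervals overlapped. In mouse 1 the rule of exactly 1 segment kept 54.3% of progenitor-like and 65.3% of effector-like cells. Taking the segment with most UMIs instead moved Trbv13-3 over all T cells of mouse 1 from 11.2% to 14.5%. The gap between classes may therefore depend on which cells the rule kept. Cells of a clone share a segment, so these intervals are narrower than the spread between clones.

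**Figure D4:**
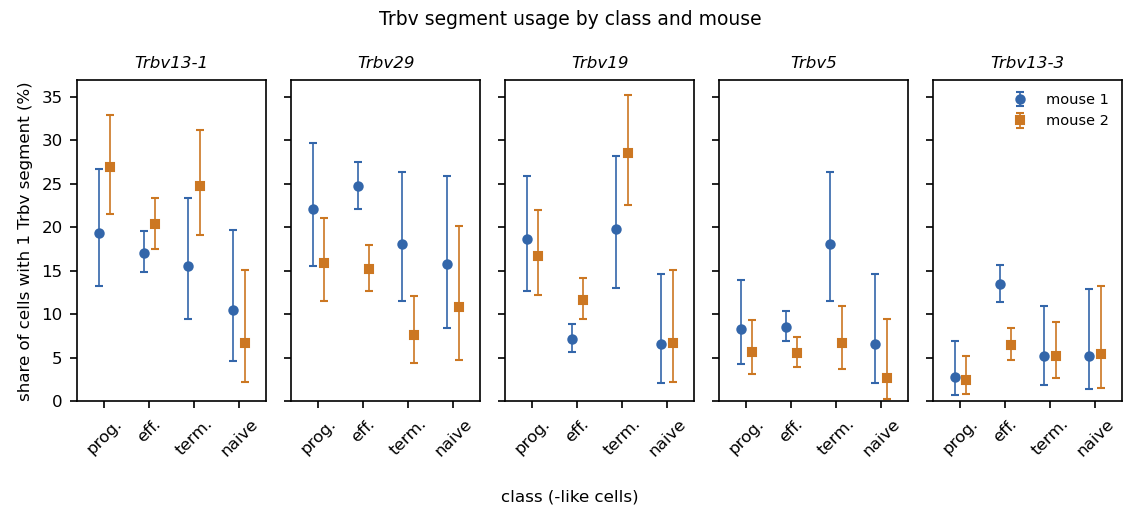
Share of cells using each of 5 Trbv segments, in percent of cells with UMIs of exactly 1 Trbv segment, in progenitor-, effector-, terminal- and naive-like cells of mouse 1 (blue circles) and mouse 2 (orange squares); error bars are exact 95% intervals for counting error. Trbv19 is higher in terminal-like cells (19.8% and 28.6%) than in effector-like cells (7.18% and 11.7%) in both mice. Progenitor-like cells stand at 18.6% and 16.7%, also above effector-like cells.

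The log2 differences between classes in mouse 1 and mouse 2 correlated across genes, which are not independent replicates. Pearson's r was 0.497 for progenitor-like against terminal-like cells, 0.478 for effector-like against terminal-like, 0.608 for progenitor-like against effector-like, 0.221 for interferon-like and 0.766 for cycling-like cells against the others, and Spearman's rho was 0.384, 0.401, 0.501, 0.164 and 0.646. Among genes with at least 100 UMIs in each mouse, r was 0.794, 0.676, 0.755, 0.260 and 0.828. Of the genes given in full, Gzmb (ENSMUSG00000015437) lies on chromosome 14 at 56258838 to 56262260, S1pr1 (ENSMUSG00000045092) on chromosome 3 at 115710433 to 115715072, Lag3 (ENSMUSG00000030124) on chromosome 6 at 124904361 to 124911705 and Klrk1 (ENSMUSG00000030149) on chromosome 6 at 129610323 to 129623864 of build GRCm38. Bcl2 (ENSMUSG00000057329) lies on chromosome 1 at 106538178 to 106714274, Ly6a (ENSMUSG00000075602) on chromosome 15 at 74994877 to 74998031, Tapbp (ENSMUSG00000024308) on chromosome 17 at 33915899 to 33929292 and Hmmr (ENSMUSG00000020330) on chromosome 11 at 40701395 to 40733422. All 8 are annotated as protein-coding genes.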

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

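Library size scaling, thinning before clustering, the left-out S100a9-rich cell and the left-out cluster 3 were chosen after seeing the data, and the other alternatives were planned. Of the results for single named genes in settings with a test, 3011 stayed on their side of the threshold, 201 were no longer past it, 3 newly passed and 3 reversed. Most of these losses came in 4 settings, 49 of 190 results with DESeq2's Wald test, 29 of 185 with count splitting, 18 of 190 without the replicate block and 17 of 114 with fixed gates. By comparison, 121 of 635 results were lost for interferon-like cells, and 35 of 669, 26 of 642, 13 of 601 and 6 of 671 for effector-like against terminal-like, progenitor-like against terminal-like, cycling-like and progenitor-like against effector-like cells. Among interferon-like cells Cst7 lost its call in 14 of 17 settings, Hif1a in 13, Pdcd1 and Tnfsf10 in 12, Fkbp2 in 10 and Cd48 in 9, and mt-Co3 lost it in 11 of 18 for effector-like against terminal-like cells. The reversals, all with fixed gates in progenitor-like against terminal-like cells, were Il18r1 (-0.32), Klrk1 (-0.75) and Klrd1 (-0.11). Of the other values, 192 moved by less than the spread between mice, or by less than 1.5 times for counts, and 57 moved further, as follows. The causes were not tested, except that DESeq2 recovered fewer known changes than edgeR in simulated data and that count splitting leaves fewer UMIs by construction. DESeq2 also made 0 false calls there, while edgeR's share of false calls reached 8.66%. Its lower counts on the real data may therefore hold fewer false calls as well as fewer true ones.

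In the order of the comparisons, DESeq2's Wald test called 170, 221, 316, 76 and 808 genes. Without the replicate block, 552 genes passed for effector-like against terminal-like, 853 for progenitor-like against effector-like and 169 for interferon-like cells. With count splitting, 473, 732, 128 and 1516 genes passed in the comparisons other than progenitor-like against terminal-like, and fixed gates gave 210 for effector-like against terminal-like cells. With an estimated correlation 0 gene lists were called in each comparison, and fry called 0, 1, 1 and 0 in those other than interferon-like cells. Simulated lists with a true shift were also missed with an estimated correlation, with p from 0.0711 to 0.110. Library size scaling in place of TMM moved the median of all tested genes to -0.17, 0.03, -0.20, -0.19 and -0.05 on the log2 scale.

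The effector-like share was 60.3% with no cell filter, 43.0% with doublets kept, 42.4% at Leiden resolution 1.2, 40.7% with 1000 and 63.2% with 3000 variable genes. It was 40.7% without cell cycle genes, 60.0% with count splitting, 22.6% with fixed gates and 62.0% with cells thinned to 1500 UMIs before clustering. The progenitor-like share was 18.9% with count splitting. The cycling-like share was 8.51% with no cell filter and 15.6% with cell cycle genes left out, where it took in most of cluster 3. The naive-like share was 4.93% with the stricter cell filter (800 genes, 5% mitochondrial UMIs), 4.54% with 3000 variable genes and 3.31% with count splitting. Trbv5 usage was 6.22% when at least 2 UMIs were asked for.

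Shares of cells with a UMI followed depth, in the order progenitor-, effector- and terminal-like cells. Without thinning they were 24.5%, 25.4% and 2.22% for S1pr1, 23.9%, 39.96% and 3.29% for Klrk1, and 7.90%, 63.0% and 48.5% for Gzmb. Thinned to 1000 UMIs, S1pr1 was seen in 10.3% of effector-like cells, Klrk1 in 9.19% of progenitor-like and 21.5% of effector-like cells, and Gzmb in 1.98%, 39.5% and 29.8%. Correlations between the mice rose to 0.794, 0.676, 0.755 and 0.828 with at least 100 UMIs in each mouse, in the comparisons other than interferon-like cells. Leaving out a mouse gives a fold change without a test, so no counts were made, and fixed gates define no interferon-, cycling- or naive-like cells. At 1.5-fold, edgeR recovered 10.9% of changed genes in simulated data for interferon-like cells.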

Other observations

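The 3 contrasts described first and the values of Igkc were chosen after the clusters had been seen, while the predictions of the 4 tests weighed further on were written before their results. Naive-like cells carried fewer transcripts of effector function and adhesion than progenitor-like cells. Itgb1 stood at 56.2 ± 31.0 CPM against 658 ± 33.4 (log2 fold change -3.50, adjusted p = 2.72e-120, lower in 2 of 2 mice), and Id2 at 106 ± 4.54 against 331 ± 8.97. Of 5106 genes 642 passed edgeR's test, 357 higher and 285 lower. Cytotoxic and effector molecules were lower for 11 of 14 members, 0 higher and 3 not passed, both over all genes and adjusted over the list alone, with Ccl5 at -3.14 and Nkg7 at -1.71 (camera adjusted p = 1.34e-32; adjusted p = 0.325 with an estimated correlation). Trafficking and adhesion genes were lower for 10, higher for 2 and not passed for 6 of 18 (11 and 3 adjusted over the list alone), Itga4 at -2.50 (camera adjusted p = 4.32e-09; adjusted p = 0.325 with an estimated correlation). Costimulatory receptors were lower for 7, higher for 0 and not passed for 4 of 11 (9 lower over the list alone), Slamf7 at -2.91 (camera adjusted p = 9.56e-05; adjusted p = 0.325 with an estimated correlation). Cytosolic ribosomal proteins were higher for 76 of 82, 0 lower and 6 not passed (77 over the list alone), Rps20 at 1.02 (camera adjusted p = 5.91e-190; adjusted p = 0.325 with an estimated correlation). Il6ra, encoding the interleukin 6 receptor, was higher by 3.63 on the log2 scale. Outside the lists and the clustering genes Ramp1, Tmem108 and Als2cl were highest (5.20, 4.26 and 3.17) and S100a6, an effector marker, Rora and Lgals1, also an effector marker, lowest (-4.54, -3.89 and -2.42).

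Clusters 2 and 3 both carried more Cxcr3, a chemokine receptor of activated T cells, and fewer NK receptor transcripts than cluster 1, the larger effector-like cluster. Cxcr3 stood at 366 ± 38.8 CPM in cluster 2 against 69.1 ± 3.70, and at 285 ± 44.3 in cluster 3 against 70.5 ± 3.77 (log2 fold changes 2.40 and 2.04, adjusted p = 1.03e-109 and 1.14e-63, higher in 2 of 2 mice). In cluster 2, 443 of 6608 genes passed (326 higher and 117 lower), and in cluster 3, 558 of 7032 (353 higher and 205 lower). NK receptors were lower for 5 of 6 with 0 higher and 1 not passed in cluster 2 (6 adjusted over the list alone), Klrd1 at -1.38 (camera adjusted p = 4.29e-24; adjusted p = 0.505 with an estimated correlation). In cluster 3 they were lower for 6 of 6, both ways of adjusting, Klrc1 at -1.03 (camera adjusted p = 1.04e-23; adjusted p = 0.434 with an estimated correlation). Cluster 2 had Ctla4 at 3.02, Ier3 at 2.30, Tigit at 1.54 and Gzmb at -0.64, and cytosolic ribosomal proteins higher for 71 of 82 with 0 lower and 11 not passed (76 adjusted over the list alone; camera adjusted p = 3.29e-184; adjusted p = 0.505 with an estimated correlation). In cluster 3, inhibitory receptors were higher for 4 of 9, 0 lower and 5 not passed (6 adjusted over the list alone), Tigit at 1.42 and Pdcd1 at 0.82 (camera adjusted p = 1.29e-07; adjusted p = 0.434 with an estimated correlation). Immediate early genes there were lower for 10, higher for 1 and not passed for 5 of 16 (12 and 1 adjusted over the list alone; camera adjusted p = 6.27e-10; adjusted p = 0.434 with an estimated correlation). Cells of cluster 3 had a median of 4326 and 3505 UMIs against 2194 and 1944.5 in cluster 1, and 13.2% and 13.0% of them lay above the 90th percentile of their library's doublet scores, against 5.16% and 5.59%.

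Naive-like cells made up 4.04% and 4.34% of the cells although the sort asked for tetramer binding. An antigen-experienced but quiescent state with levels near those of progenitor-like cells is argued against. The median log2 difference of Cd44, Pdcd1, Ccl5 and Nkg7 from progenitor-like cells was -2.43 in the mouse nearer to 0 (-2.68 in the other), below the bound of -1 set in advance. Naive-like cells held Ccl5 at 2115 and 1581 CPM, Nkg7 at 881 and 1079, Cd44 at 13.4 and 10.6 and Pdcd1 at 2.23 and 2.64. With progenitor-like cells as the only reference, resting antigen-experienced cells lower in these genes are not excluded. Cells carried through the sort without binding are a candidate explanation, since they would use many V segments, and the effective number of Trbv segments was 13.5 and 15.5. In equal-sized draws of progenitor-like cells, the central 95% ran from 6.16 to 8.74 and from 5.48 to 9.13. Naive cells that do bind the tetramer stay open, as the binding of each cell was not recorded in the data used here.

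Terminal-like cells were 2.16 times as frequent in mouse 2 as in mouse 1. A different depth of the libraries is argued against, because with every cell thinned to 1500 UMIs and clustered again the ratio was 2.25, above the bound of 1.5 set in advance. A difference between the animals, their clones or the handling of each spleen stays open and was not tested, since each mouse has 1 library.

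With cell cycle genes left out of the clustering, cycling cells joined the cluster that held most cells of cluster 3, the effector-like cluster with Lgals3 and Vim. More UMIs per cell in both is argued against as the cause, since at 1500 UMIs per cell 88.7% of the cycling cells of mouse 2 and 92.4% of those of mouse 1 still fell there (84.8% and 88.1% at full depth). Cells of cluster 3 that have recently divided, and cell pairs read as 1 cell, stay open and were not tested.

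Igkc, the constant region of the immunoglobulin kappa chain, was seen in 0 of 114 and 0 of 106 naive-like cells, which allows shares of up to 2.63% and 2.83%. It was seen in 16.1% and 8.71% of progenitor-like cells, 23.2% and 26.8% of cycling-like cells, 6.55% and 5.09% of effector-like cells and 76.2% and 90.9% of B cells. Median depths were 4299.5 and 3920 UMIs in naive-like, 3327 and 2973 in progenitor-like, 7907 and 6497.5 in cycling-like, 2384 and 2063 in effector-like and 2953 and 3001 in B cells. Against progenitor-like cells Igkc was at least 16.6-fold lower in naive-like cells, with 0 against 118 UMIs.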
